A study of Homo sapiens with 6 samples.

How the data were processed

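The data are mRNA sequencing of SH-SY5Y cells, a human neuroblastoma line with neuroblast-like properties. Per the labels' protocols, cells received lentivirus with a short hairpin RNA against CSA, against CSB or a control hairpin, were selected with puromycin and were kept in culture for 2 to 3 weeks. CSA is the product of ERCC8 and CSB of ERCC6. The labels' genotype field calls the depleted cells mutants, whereas the protocols describe hairpins, so they are called knockdowns here. Total RNA was taken with Trizol and libraries were made from 1 µg with the Illumina TruSeq RNA kit, per the labels' protocols. Sequencing was paired-end on an Illumina HiSeq, per the labels' series design. There were 3 groups of 2 libraries: control, CSA knockdown and CSB knockdown. Whether the 2 libraries of a group came from separate transductions or from 1 cell pool is not given in the sources used here, and neither are the hairpin sequences.

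Alignment to hg38 with HISAT2 2.0.4 and read checks with FastQC are listed per the submitters' processing notes. The counting tool, its strand setting, the annotation release and the normalization tool are not given in the sources used here. The value columns are headed FPKM per the file headers, but no gene length enters them. In each of the 6 libraries, 100% of the deposited values were whole multiples of the smallest value, with a tolerance of 0.01 of that step. The deposited unit is therefore a signal, namely gene read counts divided by one size factor per library, and is called the scaled count here. A gene without reads has no entry in a library and was taken as 0. Reads per gene were recovered by dividing each scaled count by the library's smallest value. The test set in advance was edgeR's quasi-likelihood test with TMM scaling for raw counts, and limma for normalized units such as FPKM. The values as deposited were neither, and the test set for normalized units was kept. Count models on the recovered reads, that edgeR test among them, were run as alternatives after the data were seen.

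The recovered reads numbered 21288892 and 21983668 in the control libraries, 19368272 and 22308609 in the CSA knockdown, and 20075100 and 26758162 in the CSB knockdown. Genes are named by the symbols in the deposited tables, which pair them with Ensembl identifiers and hg38 positions. Of 32575 genes listed, 31618 (97.1%) had a current symbol for their Ensembl identifier. GC content came from GENCODE v29 and was at hand for 27874 of the tested genes (98.2%). Gene length and genomic span came from the deposited tables. Because the strand setting is not stated, overlapping and antisense genes were treated as uncertain. Genes with near-identical copies, such as histones, ribosomal protein genes, the ACTA2 and ACTG2 pair and the pseudogene FGFR3P5, were treated likewise.

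Genes with a mean scaled count of at least 1 in at least 1 group were tested, 28388 in all. limma (version 3.58.1, R 4.3.3) was fitted with a mean-variance trend to log2(scaled count + 1). The 3 groups entered one fit of 6 libraries, with 3 residual degrees of freedom. The comparisons were CSA knockdown versus control, CSB knockdown versus control and CSB knockdown versus CSA knockdown. Genes rose or fell where the Benjamini-Hochberg adjusted p was below 0.05, and every adjusted p of a gene comes from this limma test unless another tool is named. Adding 1 before the logarithm makes the fold change of genes with few reads smaller than their ratio of levels. For genes with 1 to 3 reads in a group, the ratio of reads is given with an exact 95% interval. For genes without reads in a group, a lower bound against a floor of 3 reads per library is given, or no fold where both groups lay at or under that floor. These intervals and floors cover counting error only. The p-values measure the spread between these 6 libraries, which can be technical.

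A set of 34 gene lists was written before the data were examined, as were the comparisons, the rule for named genes and most alternatives. The lists covered DNA repair, p53 targets, the cell cycle and apoptosis. They covered neuronal and neuroblastoma cell identity, matrix, cytokines, stress responses and metabolism. Further lists held RNA synthesis and ribosome genes, imprinted genes, histones and markers of other cell types. Each was tested against all other genes with camera (limma) at a preset inter-gene correlation of 0.01, with adjustment over the 34 lists. An estimated correlation and fry, which tests whether a list's genes move one way on balance without reference to other genes, were the alternatives. With an estimated correlation, camera takes its p from the fit's 3 residual degrees of freedom, and at the preset from far more, set by the number of genes. List members were also counted after adjustment over the list alone.

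Named genes were ERCC8, ERCC6, its fusion entries and NDN. To these were added, per comparison with control, the 8 largest rises and 8 largest falls among genes past the test. Such a gene needed both knockdown libraries on one side of both control libraries and a mean of at least 5 in the higher group. For CSB versus CSA knockdown the 5 largest in each direction were taken. From each list came up to 2 rises and 2 falls with the smallest adjusted p. For both knockdowns, 5 genes per direction were taken by the smaller of their 2 fold changes.

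Overlap of the comparisons with control was set beside the overlap of independent lists. It was also set beside 50 simulated sets of 6 unchanged libraries that shared their controls, since both comparisons use the same 2 control libraries. The test was tried on simulated reads for the real genes, with 50 genes changed at each of 4 sizes. Genes with the fewest reads in control were not among those changed. Far fewer genes were changed than were called in the data, and all groups were given the same spread, so the rates may not carry over. At fold changes of 1.25, 1.5, 2 and 4 it recovered 28%, 54%, 76% and 100% of the changed genes for CSA knockdown over 27237 genes. For CSB knockdown over 27311 genes it recovered 22%, 82%, 82% and 94%. False calls were 0 of 129 for CSA and 1 of 141 (0.709%) for CSB.

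Alternatives were other scalings (median centring, quantile normalization), filters, pseudocounts, thresholds, limma without the trend, fits of only the 4 libraries compared, and a replicate block. The removal of GC or length trends and the omission of each library in turn were tried as well. Added after the data were seen were edgeR 4.0.16 with TMM, RLE and upper quartile scaling, DESeq2 1.42.0 and limma-voom on recovered reads, size factors recomputed over the 6 libraries, and reads thinned to equal totals. Of these, edgeR with TMM scaling had been set in advance for raw counts. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. With 2 libraries per group, other splits of the samples and a test of single libraries against their group were not run. Between the 2 libraries of a group, chi-square per degree of freedom was 1.95 for control, 5.06 for CSA knockdown and 2.66 for CSB knockdown. No deposited value column was left out.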

Results

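Messenger RNA was sequenced from SH-SY5Y neuroblastoma cells depleted of CSA or CSB by RNA interference and from cells with a control hairpin, with 2 libraries in each of the 3 groups. CSA (gene ERCC8) is part of a ubiquitin ligase and CSB (gene ERCC6) is a chromatin remodeller, and both act in transcription-coupled repair. Loss of either causes Cockayne syndrome, a disorder with neurodegeneration. The comparisons ask which transcripts depend on each protein in a neuronal cell line. The libraries held 19368272 to 26758162 gene-assigned reads. Mitochondrial transcripts took 5.73 to 6.51% of the scaled counts. On 13397 genes with a mean scaled count of at least 50, the first principal component held 71.0% of the variance. It placed the control libraries at -1.04 and -1.90, between the CSA knockdown (-33.9 and -32.6) and the CSB knockdown (34.7 and 34.6). The second component (21.3%) separated the controls, at 20.3 and 22.5, from all 4 knockdown libraries, at -13.1 to -9.70.

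Levels are mean scaled counts ± SD of the 2 libraries of a group, and a value in parentheses after a gene is its log2 fold change ± SE. After a count of list members, square brackets hold the lowest and highest count with any one of the 6 libraries left out. Counts adjusted over the list alone are given where they differ from those adjusted over all genes.

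ERCC8, on the minus strand of chromosome 5 from 60873831 to 60945073 (hg38), had scaled counts of 219 and 217 in the control libraries. In the CSA knockdown they were 61.8 and 57.2 (log2 fold change -1.86 ± 0.13, adjusted p = 8.8e-07). The CSB knockdown libraries had 186 and 215, a difference from control that did not pass the test (log2 fold change -0.12 ± 0.13, adjusted p = 0.552). ERCC6, on the minus strand of chromosome 10 from 49455368 to 49539538, had scaled counts of 615 and 593 in the controls and 258 and 302 in the CSB knockdown (log2 fold change -1.11 ± 0.08, adjusted p = 2.1e-06). It stood at 618 and 611 in the CSA knockdown (log2 fold change 0.03 ± 0.08, adjusted p = 0.883). Each protein-coding gene was thus lower in the group named after it, and the values are per gene, so they do not tell its transcripts apart. Reads assigned to the fusion transcript ERCC6-PGBD3 and to PGBD3, which lie within ERCC6, numbered at most 1 and 2 in any library. Since the counting tool is not given, reads in shared exons may have been given to ERCC6 or left out. Expression of the fusion therefore cannot be read from these counts.

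**Figure D1:**
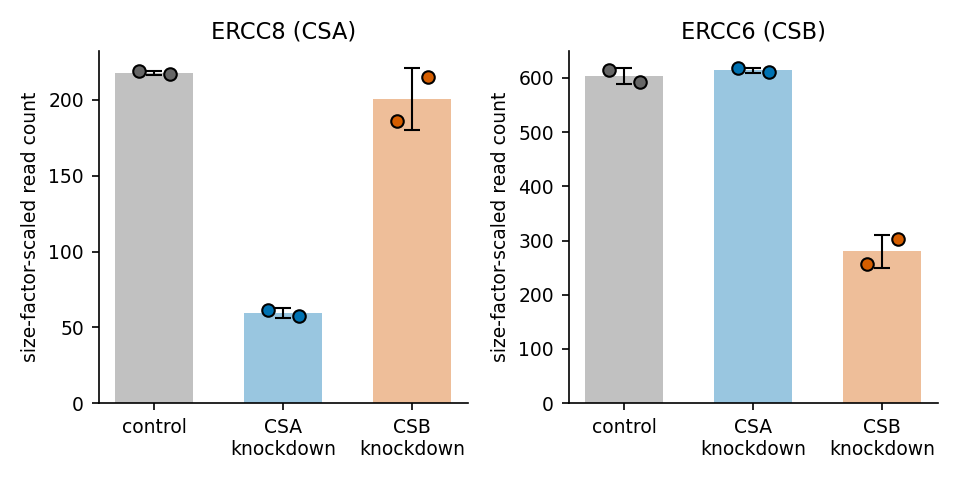
Scaled counts (y axis, read counts divided by the library's size factor) of ERCC8 and ERCC6 by group on the x axis; bars are means, error bars SDs and points the 2 libraries of each group. ERCC8 had a mean of 59.5 in the CSA knockdown against 218 in control, and ERCC6 a mean of 280 in the CSB knockdown against 604 in control.

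In cells depleted of CSA, lists of synaptic and neuronal differentiation genes shifted up, and those of matrix, cell cycle and p53 target genes down, by camera at the preset correlation. None of these shifts passed with an estimated correlation. The proneural transcription factor NEUROG2 went from 22.9 ± 7.12 to 663 ± 29 (log2 fold change 4.83 ± 0.35, adjusted p = 1.4e-06). VSTM2A rose from 100 ± 11.9 to 1305 ± 1.05 (log2 fold change 3.70 ± 0.10, adjusted p = 2.3e-09), and CA10, a carbonic anhydrase-like protein of synapses, from 20.1 ± 5.28 to 268 ± 3.06 (log2 fold change 3.69 ± 0.20, adjusted p = 1.6e-07). The smooth muscle actins ACTA2 and ACTG2, near-identical genes whose reads can be mixed, fell together. ACTA2 went from 569 ± 7.73 to 53.6 ± 16.0 (log2 fold change -3.42 ± 0.16, adjusted p = 4.9e-08) and ACTG2 from 237 ± 10.1 to 8.56 ± 1.38 (log2 fold change -4.64 ± 0.22, adjusted p = 6.3e-08).

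Among the other large rises were PTCHD1 (4.79 ± 0.45), a Patched-domain protein, and CBLN4 (3.98 ± 0.48), a synaptic organizer of the cerebellin family. SHISA9, an auxiliary subunit of AMPA receptors, went from 1 to 126 reads (log2 fold change 5.52 ± 0.53, adjusted p = 1.4e-05). The ratio was 131 (95% interval 23.0 to 5196). HS3ST3B1, a heparan sulfate sulfotransferase, rose as well (log2 fold change 3.56 ± 0.64, adjusted p = 0.00183), with a ratio of 32.1 (95% interval 5.35 to 1309). VSTM2A-OT1 (3.53 ± 0.42) overlaps VSTM2A and cannot be separated from it without strand. Large falls were seen for the cytoskeletal linker EPPK1 (log2 fold change -4.14 ± 0.32, adjusted p = 3.0e-06), the small GTPase RAB7B (log2 fold change -3.29 ± 0.19, adjusted p = 2.4e-07) and KIAA1644 (-3.29 ± 0.35). The VEGF receptor FLT1 fell (log2 fold change -3.48 ± 0.55, adjusted p = 6.9e-04) to a read ratio of 0.0345 (95% interval 0.000846 to 0.208). GIPC3 fell (log2 fold change -3.66 ± 0.50, adjusted p = 2.4e-04) to a ratio of 0.0493 (95% interval 0.00578 to 0.190). The TNF receptor family member TNFRSF9 fell from 48.0 ± 1.04 to 4.42 ± 3.19 (log2 fold change -3.31 ± 0.49, adjusted p = 4.4e-04). The calls for HS3ST3B1 (without either control or CSA knockdown library), GIPC3 and TNFRSF9 (either control or CSB knockdown library) and FLT1 (control replicate 1) ended, with adjusted p up to 0.109, 0.0686, 0.0741 and 0.0579.

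Neuronal lists shifted up at the preset correlation. Of 44 tested genes of synaptic vesicles and exocytosis, 25 rose [11 to 16] and 6 fell [3 to 4], or 26 and 6 adjusted over the list alone, with a median of 0.25 and adjusted p = 1.8e-07 by camera (adjusted p = 0.0810 with an estimated correlation). The granins CHGA (0.71 ± 0.06), CHGB (1.09 ± 0.06) and SCG2 (1.01 ± 0.05), cargo of dense-core vesicles, rose, while SYT4 (-0.60 ± 0.05) and SV2C (-0.97 ± 0.06) fell. Of 38 genes of neuronal differentiation, 16 rose [9 to 14] and 5 fell [3 to 4], or 17 and 5 adjusted over the list alone (adjusted p = 5.6e-04 by camera; adjusted p = 0.0810 with an estimated correlation). The growth cone protein GAP43 (1.06 ± 0.06) and the microtubule protein DCX (0.89 ± 0.06) were among the rises and DPYSL3 (-0.92 ± 0.05) among the falls. Of 32 neuronal ion channels and receptors, 16 rose [7 to 13] and 5 fell [3 to 5], or 16 and 6 adjusted over the list alone (adjusted p = 0.00274 by camera; adjusted p = 0.0937 with an estimated correlation). The AMPA receptor subunit GRIA2 (1.97 ± 0.08) and the nicotinic receptor subunit CHRNA3 (0.72 ± 0.05) rose, and the adrenergic receptor ADRA2A (-2.08 ± 0.10) and the potassium channel KCNJ3 (-1.56 ± 0.15) fell.

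Proliferation genes fell. Of 38 genes of G2/M phase and mitosis, 35 fell [26 to 33] and 0 rose [0], or 38 and 0 adjusted over the list alone, with a median of -0.54 (adjusted p = 5.9e-31 by camera; adjusted p = 0.0810 with an estimated correlation). BIRC5 (-1.13 ± 0.06), KIF20A (-0.89 ± 0.05) and TOP2A (-0.65 ± 0.05) were examples. Of 38 DNA replication and S phase genes, 32 fell [9 to 22] and 1 rose [1], or 34 and 1 adjusted over the list alone (adjusted p = 1.9e-17 by camera; adjusted p = 0.0642 with an estimated correlation). The helicase subunits MCM4 (-0.59 ± 0.05) and MCM6 (-0.51 ± 0.05) fell and CCNE1 (0.51 ± 0.07) rose. Among 30 p53 targets, 21 fell [9 to 12] and 1 rose [0 to 1], with a median of -0.35 (adjusted p = 1.9e-09 by camera; adjusted p = 0.0642 with an estimated correlation). ZMAT3 fell from 1885 ± 60.9 to 630.3 ± 39.0 (log2 fold change -1.58 ± 0.06, adjusted p = 1.4e-08) and GDF15 from 380.0 ± 0.0660 to 133 ± 17.4 (log2 fold change -1.52 ± 0.09, adjusted p = 4.4e-07). BTG2 rose (0.31 ± 0.06), a call that ended without either control library (adjusted p up to 0.0631). Of 27 apoptosis regulators, 11 fell [6 to 8] and 5 rose [2 to 3], or 12 and 6 adjusted over the list alone, with a median of -0.08, a mean of 0.01 and adjusted p = 0.107 by camera. BCL2 (-0.66 ± 0.06) and BMF (-0.69 ± 0.06) fell.

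Matrix and mesenchymal lists shifted down as well. Of 32 matrix genes, a list that also holds fibroblast markers, 20 fell [12 to 19] and 1 rose [0 to 1], or 23 and 1 adjusted over the list alone, with a median of -0.64 (adjusted p = 3.5e-16 by camera; adjusted p = 0.0810 with an estimated correlation). FN1, which encodes fibronectin, fell from 9018 ± 7.97 to 2369.9 ± 163 (log2 fold change -1.93 ± 0.06, adjusted p = 5.0e-09), and FBN1 (-1.36 ± 0.06) and SPARC (-1.12 ± 0.05) fell too. Of 30 markers of mesenchymal-type neuroblastoma, 18 fell [11 to 12] and 1 rose [1], or 20 and 3 adjusted over the list alone (adjusted p = 4.9e-10 by camera; adjusted p = 0.0642 with an estimated correlation). VIM (-0.84 ± 0.05), SOX9 (-1.15 ± 0.07) and YAP1 (-1.09 ± 0.09) were among the falls. Of 16 NF-kB targets and cytokines, 8 fell [2 to 4] and 0 rose [0], or 10 and 0 adjusted over the list alone (adjusted p = 2.6e-05 by camera; adjusted p = 0.0810 with an estimated correlation). The chemokine CCL2 (-2.02 ± 0.13) and TRAF1 (-2.19 ± 0.27) fell. Of 26 immediate-early genes, 12 fell [5 to 7] and 4 rose [1 to 3], or 12 and 5 adjusted over the list alone, with a median of -0.32 (adjusted p = 0.0233 by camera; adjusted p = 0.447 with an estimated correlation). CYR61 (-2.37 ± 0.08) and KLF6 (-0.63 ± 0.06) fell and DUSP4 (0.53 ± 0.05) rose. That list's shift ended without control replicate 1 (0.0554), CSA replicate 1 (0.194) or CSB replicate 1 (0.0552) or 2 (0.0543), and under 4 of 7 scalings (adjusted p up to 0.115).

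Stress response and metabolic lists went mostly down. Among 30 ATF4 targets, 20 fell [8 to 16] and 1 rose [1], or 22 and 1 adjusted over the list alone (adjusted p = 6.4e-11 by camera; adjusted p = 0.0810 with an estimated correlation). SHMT2 (-0.97 ± 0.05) and PSAT1 (-0.66 ± 0.08), enzymes of serine and folate metabolism, fell and VLDLR (1.17 ± 0.06) rose. The PSAT1 call ended without either CSB library (adjusted p up to 0.0514). Of 29 antioxidant genes, 15 fell [6 to 11] and 0 rose [0], or 18 and 0 adjusted over the list alone (adjusted p = 1.2e-07 by camera; adjusted p = 0.0810 with an estimated correlation). NQO1 (-0.69 ± 0.08) and TXNRD1 (-0.55 ± 0.05) fell. Cytosolic chaperones had 20 members, of which 7 fell [3 to 5] and 0 rose [0], or 9 and 1 adjusted over the list alone (adjusted p = 0.00646 by camera; adjusted p = 0.144 with an estimated correlation). The small heat shock protein CRYAB fell from 54.3 ± 0.899 to 5.09 ± 0.460 (log2 fold change -3.19 ± 0.28, adjusted p = 6.7e-06). Of 24 endoplasmic reticulum chaperones and related genes, 7 fell [4 to 6] and 4 rose [0 to 1], or 11 and 4 adjusted over the list alone (adjusted p = 0.0209 by camera; adjusted p = 0.144 with an estimated correlation). HYOU1 (-1.22 ± 0.07) and PDIA4 (-0.35 ± 0.05) fell. Glycolysis and hypoxia genes numbered 30, of which 15 fell [7 to 11] and 1 rose [0 to 1], or 16 and 4 adjusted over the list alone (adjusted p = 4.9e-04 by camera; adjusted p = 0.0890 with an estimated correlation). PFKFB3 (-1.31 ± 0.06) and EGLN3 (-1.28 ± 0.07) fell. The unfolded protein list lost its shift in 9 of 27 alternatives, among them 5 of 7 scalings (adjusted p up to 0.102 by camera).

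Of 40 ribosomal protein genes, 12 rose [0 to 5] and 0 fell [0], or 15 and 1 adjusted over the list alone, with a median of 0.15 (adjusted p = 3.8e-07 by camera; adjusted p = 0.447 with an estimated correlation; adjusted p = 0.0744 by fry). RPL3 (0.31 ± 0.06) and RPLP0 (0.28 ± 0.05) rose, calls that ended without either control or either CSB library (adjusted p up to 0.129 and 0.142). Of 40 genes of RNA polymerase I and ribosome biogenesis, 9 fell [1 to 5] and 0 rose [0], or 10 and 0 adjusted over the list alone (adjusted p = 0.0155 by camera; adjusted p = 0.130 with an estimated correlation). The RNA helicase DDX21 (-0.39 ± 0.05) fell. The shift of this list ended in 9 of 27 alternatives, among them 4 of 7 scalings (adjusted p up to 0.119 by camera) and the omission of CSA replicate 1. Of 41 genes of transcription-coupled and nucleotide excision repair, 9 fell [2 to 7] and 2 rose [0 to 1], with a median of -0.07 (adjusted p = 0.0233 by camera; adjusted p = 0.143 with an estimated correlation). ERCC8, which the hairpin targets, counts among the falls, and the list was not tested without it. DDB2, a damage sensor and p53 target, fell as well (-0.48 ± 0.06). The repair list lost its shift in 10 of 27 alternatives, among them 5 of 7 scalings (adjusted p up to 0.165 by camera) and the omission of control replicate 2.

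Oxidative phosphorylation genes of the nucleus (43 tested: 5 fell [0 to 2] and 2 rose [0 to 1]; adjusted p = 0.571) did not pass camera's test in the CSA knockdown. Neither did mitochondrially encoded transcripts (13: 1 rose [0 to 1] and 1 fell [0 to 1]; adjusted p = 0.889) and genes of cholesterol and fatty acid synthesis (32: 5 rose [2 to 3] and 5 fell [1 to 5], or 5 and 10 adjusted over the list alone; adjusted p = 0.571). Autophagy and lysosome genes (36: 8 fell [6 to 8] and 6 rose [2 to 4], or 9 and 7 adjusted over the list alone; adjusted p = 0.571) had GABARAPL1 (0.85 ± 0.09) among the rises and PSAP (-0.82 ± 0.05) and CTSB (-0.42 ± 0.05) among the falls. In the imprinted list (25: 8 fell [1 to 3] and 5 rose [4], or 9 and 6 adjusted over the list alone; adjusted p = 0.750) the median was -0.12 and the mean 0.07. IGF2 and H19, neighbours on chromosome 11, both rose, IGF2 from 665 ± 74.7 to 3678 ± 130.3 (log2 fold change 2.47 ± 0.09, adjusted p = 6.8e-09) and H19 by 1.79 ± 0.07, and DLK1 rose by 0.94 ± 0.07. NDN, which encodes the neuronal growth suppressor necdin, fell from 116 ± 26.1 to 72.2 ± 3.66 (log2 fold change -0.66 ± 0.17, adjusted p = 0.0155), but the call ended with the omission of any one of the 6 libraries (adjusted p up to 0.234 without CSA replicate 2).

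In total 5334 of 28388 genes changed in the CSA knockdown, 2376 up and 2958 down, of which 328 and 521 changed at least 2-fold. A fit of only the control and CSA libraries called 2460. The excess of falls turned with edgeR and upper quartile scaling (3214 up and 3034 down) and with the gene length trend removed (2879 and 2714). Leaving out 1 library gave 1539 (control replicate 1), 1512 (control replicate 2), 2882 (CSA replicate 1), 2759 (CSA replicate 2), 2457 (CSB replicate 1) and 2446 (CSB replicate 2) genes. camera called 18 of 34 lists at its preset correlation, and 0 with an estimated correlation, where 13 had an unadjusted p below 0.05; fry called 23.

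In cells depleted of CSB, lists of cholesterol synthesis, neuronal and S phase genes shifted down, and those of p53 targets, matrix and autophagy up, by camera at the preset correlation. With an estimated correlation the neuronal, matrix and autophagy shifts did not pass. INSM2, a zinc finger factor of neuroendocrine cells, fell from 403 ± 4.42 to 15.0 ± 0.963 (log2 fold change -4.66 ± 0.09, adjusted p = 4.9e-11), and the growth factor IGF2 from 665 ± 74.7 to 49.2 ± 1.98 (log2 fold change -3.73 ± 0.09, adjusted p = 2.2e-10). ARHGAP36 fell from 2635 ± 51.5 to 244 ± 5.40 (log2 fold change -3.43 ± 0.06, adjusted p = 2.6e-11). The neurotrophin receptor NGFR rose from 109 ± 9.99 to 1436 ± 111 (log2 fold change 3.70 ± 0.13, adjusted p = 1.1e-08). HMGCS1, an enzyme early in cholesterol synthesis, fell from 1320.4 ± 24.7 to 359 ± 14.6 (log2 fold change -1.88 ± 0.06, adjusted p = 6.7e-09).

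Further falls were those of LINC00890 (log2 fold change -4.50 ± 0.32, adjusted p = 1.2e-06) and KIAA0125 (log2 fold change -4.09 ± 0.34, adjusted p = 3.9e-06). NEUROG2, which rose in the CSA knockdown, went from 47 reads in the controls to 1 (log2 fold change -4.11 ± 0.35, adjusted p = 4.7e-06), a ratio of 0.0205 (95% interval 0.000508 to 0.120). CCDC68 went from 40 to 1 (log2 fold change -3.92 ± 0.39, adjusted p = 1.8e-05), a ratio of 0.0241 (95% interval 0.000595 to 0.142). SLC22A10 fell (log2 fold change -3.51 ± 0.63, adjusted p = 0.00139), with a ratio of 0.0820 (95% interval 0.0214 to 0.224). The transcription factor ZIC2 had 0 reads in the controls and 31 in the CSB knockdown (log2 fold change 3.94 ± 0.64, adjusted p = 7.2e-04), at least 4.91-fold higher against the floor of 3 reads per library. ITGB2-AS1, an antisense gene of uncertain strand, went from 0 to 13 reads (log2 fold change 2.83 ± 0.61, adjusted p = 0.00461), at least 2.20-fold higher. Few reads also lay behind MSC (3.08 ± 0.67), with a ratio of 22.2 (95% interval 3.6 to 912). The ratio of ELFN1 (3.59 ± 0.70) was 20.7 (95% interval 5.39 to 176) and that of SERPINB7 (2.92 ± 0.67) was 12 (95% interval 3.00 to 105). FAM19A5 (log2 fold change 2.90 ± 0.43, adjusted p = 3.4e-04) and the phospholipid flippase ATP8A2 (log2 fold change 2.91 ± 0.43, adjusted p = 3.5e-04) rose as well. Calls ended for MSC and ZIC2 without either control or CSB library (adjusted p up to 0.155 and 0.0813) and for FAM19A5 without either CSB library (0.0869). The same was true of ELFN1 without control replicate 2 or either CSB library (0.158), and of ITGB2-AS1 without either control library or CSB replicate 1 (0.0710). SERPINB7 and SLC22A10 lost theirs in 5 of 6 omissions (all but control replicate 2 and CSB replicate 2, up to 0.190 and 0.119).

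Of 32 genes of cholesterol and fatty acid synthesis, 25 fell [10 to 25] and 1 rose [0 to 1], or 27 and 1 adjusted over the list alone, with a median of -0.40 (adjusted p = 2.8e-18 by camera; adjusted p = 0.0360 with an estimated correlation). SREBF2 (-0.59 ± 0.05), the transcription factor that drives the pathway, fell. Neuronal lists shifted down at the preset correlation. Of 44 synaptic genes, 21 fell [10 to 20] and 11 rose [1 to 8], or 25 and 11 adjusted over the list alone, with a median of -0.25 (adjusted p = 6.6e-07 by camera; adjusted p = 0.0952 with an estimated correlation). CHGA fell from 14899.5 ± 609 to 3624 ± 81.4 (log2 fold change -2.04 ± 0.06, adjusted p = 3.2e-09) and SNAP25, a fusion protein of vesicles, from 2739.7 ± 51.4 to 919.6 ± 18.3 (log2 fold change -1.57 ± 0.05, adjusted p = 6.4e-09), while SV2C rose (0.70 ± 0.06). Among 38 genes of neuronal differentiation, 20 fell [9 to 19] and 8 rose [2 to 5], or 21 and 8 adjusted over the list alone (adjusted p = 1.0e-06 by camera; adjusted p = 0.0749 with an estimated correlation). GAP43 (-1.67 ± 0.06) and the neurofilament NEFL (-1.20 ± 0.05) fell, and PLXNA2 (0.74 ± 0.05) and NCAM1 (0.45 ± 0.05) rose. Of 32 ion channels and receptors, 15 fell [6 to 11] and 7 rose [2 to 6], or 15 and 11 adjusted over the list alone (adjusted p = 0.0114 by camera; adjusted p = 0.128 with an estimated correlation). CHRNA3 (-0.83 ± 0.05) and CACNA2D2 (-0.95 ± 0.06) fell, and ADRA2A (1.34 ± 0.10) and CACNA1C (1.07 ± 0.08) rose.

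Targets of p53 rose. Of 30 tested, 22 rose [15 to 21] and 1 fell [0 to 1], or 24 and 1 adjusted over the list alone, with a median of 0.50 (adjusted p = 1.9e-13 by camera; adjusted p = 0.0360 with an estimated correlation). GDF15 went from 380.0 ± 0.0660 to 1124 ± 43.7 (log2 fold change 1.56 ± 0.09, adjusted p = 3.5e-07), BTG2 from 681 ± 2.30 to 1595 ± 25.7 (log2 fold change 1.23 ± 0.06, adjusted p = 5.8e-08) and ZMAT3 from 1885 ± 60.9 to 3689.7 ± 156 (log2 fold change 0.97 ± 0.06, adjusted p = 5.2e-07). Of 27 apoptosis regulators, 12 rose [5 to 11] and 2 fell [0 to 2], or 13 and 3 adjusted over the list alone (adjusted p = 0.00920 by camera; adjusted p = 0.128 with an estimated correlation). BMF (1.71 ± 0.06) and BCL2L11 (1.07 ± 0.05), which promote cell death, and BCL2 (1.20 ± 0.06), which opposes it, rose. The apoptosis shift ended without CSA replicate 1 (0.0802), CSA replicate 2 (0.0811) or CSB replicate 2 (adjusted p = 0.0593). Of 38 S phase genes, 28 fell [7 to 25] and 2 rose [1 to 2], or 29 and 2 adjusted over the list alone, with a median of -0.28 (adjusted p = 1.1e-13 by camera; adjusted p = 0.0360 with an estimated correlation). MCM6 (-0.78 ± 0.05) fell and the licensing factor CDT1 (0.54 ± 0.05) rose. G2/M genes did not pass as a list (38: 9 fell [1 to 7] and 6 rose [0 to 7], or 11 and 7 adjusted over the list alone; adjusted p = 0.213). TOP2A rose (0.22 ± 0.05), a call that ended without either control or CSB library (adjusted p up to 0.109). In the repair list of 41, 12 fell [4 to 12] and 5 rose [2 to 5], or 13 and 7 adjusted over the list alone, with a median of -0.04 (adjusted p = 0.0105 by camera; adjusted p = 0.128 with an estimated correlation). ERCC6, which the hairpin targets, is a member and counts among the falls, and the list was not tested without it. TCEA1, an elongation factor of RNA polymerase II, fell (-0.80 ± 0.05) and DDB2 rose (0.65 ± 0.06).

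Of 32 matrix genes and fibroblast markers, 17 rose [8 to 15] and 4 fell [1 to 2], or 17 and 5 adjusted over the list alone (adjusted p = 4.4e-04 by camera; adjusted p = 0.186 with an estimated correlation). The proteoglycans VCAN (1.23 ± 0.07) and DCN (2.23 ± 0.12) rose, and the protease inhibitor TIMP3 fell (-1.92 ± 0.15). Of 30 mesenchymal markers, 12 rose [7 to 11] and 1 fell [0 to 1] (adjusted p = 2.9e-04 by camera; adjusted p = 0.0952 with an estimated correlation). VIM rose from 6843 ± 23.3 to 13786 ± 96.3 (log2 fold change 1.01 ± 0.05, adjusted p = 5.6e-08), and SOX9 rose too (1.21 ± 0.07). Immediate-early genes had 26 tested members, of which 11 rose [4 to 10] and 3 fell [0 to 2], or 13 and 4 adjusted over the list alone (adjusted p = 0.00301 by camera; adjusted p = 0.247 with an estimated correlation). KLF6 (0.80 ± 0.06) and DUSP4 (0.72 ± 0.05) rose. Of 36 autophagy and lysosome genes, 14 rose [5 to 14] and 4 fell [0 to 3], or 16 and 4 adjusted over the list alone, with a median of 0.16 (adjusted p = 0.00204 by camera; adjusted p = 0.0952 with an estimated correlation). MCOLN1, a lysosomal calcium channel, rose by 0.77 ± 0.07, the kinase ULK1 by 0.56 ± 0.05 and the protease CTSB by 0.49 ± 0.05. NF-kB targets (16: 3 fell [2 to 3] and 2 rose [0 to 2]; adjusted p = 0.0820) did not pass, although CCL2 fell (-1.56 ± 0.13).

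Several lists of energy metabolism and stress went down. Of 43 nuclear genes of oxidative phosphorylation, 18 fell [0 to 7] and 0 rose [0], or 19 and 0 adjusted over the list alone, with a median of -0.15 (adjusted p = 1.8e-07 by camera; adjusted p = 0.231 with an estimated correlation). Mitochondrially encoded transcripts (13: 3 fell [0 to 3] and 1 rose [0 to 1]) passed narrowly (adjusted p = 0.0361 by camera; adjusted p = 0.181 with an estimated correlation), with MT-ND2 at -0.29 ± 0.06. The MT-ND2 call ended without either control or CSB library (adjusted p up to 0.168). The list's shift ended in 8 of 27 alternatives, with a highest adjusted p of 0.290 over the list tests. Among these 8 were the omissions of either control or either CSB library. Cytosolic chaperones included 20 genes, of which 11 fell [4 to 10] and 3 rose [0 to 3], or 14 and 3 adjusted over the list alone (adjusted p = 1.7e-06 by camera; adjusted p = 0.0952 with an estimated correlation). HSPD1 (-0.56 ± 0.05) and HSPH1 (-0.54 ± 0.05) fell. Of 24 endoplasmic reticulum genes, 9 fell [4 to 10] and 2 rose [0 to 2], or 10 and 2 adjusted over the list alone (adjusted p = 0.00114 by camera; adjusted p = 0.0952 with an estimated correlation). CANX (-0.64 ± 0.05) and HSPA5 (-0.47 ± 0.05), abundant chaperones of that compartment, fell. ATF4 targets had 30 members, of which 15 fell [9 to 16] and 6 rose [3 to 6], or 17 and 7 adjusted over the list alone (adjusted p = 9.0e-05 by camera; adjusted p = 0.153 with an estimated correlation). PSAT1 (-1.18 ± 0.08) and GARS (-0.81 ± 0.06) fell and ATF5 (0.98 ± 0.10) rose. Antioxidant genes (29: 10 fell [4 to 10] and 5 rose [1 to 2], or 10 and 7 adjusted over the list alone) had a median of -0.07, a mean of 0.03 and a downward shift (adjusted p = 0.0114 by camera; adjusted p = 0.154 with an estimated correlation). TKT (-0.46 ± 0.05) fell and AKR1C1 (1.42 ± 0.15) rose. Of 30 glycolysis and hypoxia genes, 14 fell [6 to 13] and 4 rose [0 to 6], or 14 and 5 adjusted over the list alone (adjusted p = 3.8e-04 by camera; adjusted p = 0.0952 with an estimated correlation). LDHA (-0.64 ± 0.05) and ALDOC (-1.32 ± 0.08) fell.

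Of 40 ribosome biogenesis genes, 15 fell [2 to 13] and 3 rose [1 to 3], or 17 and 3 adjusted over the list alone (adjusted p = 3.0e-05 by camera; adjusted p = 0.0892 with an estimated correlation). Ribosomal protein genes (40: 16 rose [0 to 9] and 2 fell [0 to 1], or 20 and 2 adjusted over the list alone) had a median of 0.17 (adjusted p = 4.6e-04 by camera; adjusted p = 0.5 with an estimated correlation; adjusted p = 0.0804 by fry). Their shift ended without control replicate 1 (0.0609) or CSB replicate 1 (0.0833) and under 4 of 7 scalings (adjusted p up to 0.172). Imprinted genes (25: 9 fell [7 to 9] and 6 rose [1 to 3]) had a median of 0.06, a mean of -0.37 and a downward shift (adjusted p = 0.0114 by camera; adjusted p = 0.153 with an estimated correlation). That shift ended without CSA replicate 1 (0.0995) or 2 (0.102) or CSB replicate 1 (adjusted p = 0.0533). H19 fell from 5924 ± 244 to 841 ± 9.08 (log2 fold change -2.81 ± 0.07, adjusted p = 7.3e-10) and DLK1 from 909 ± 1.06 to 285 ± 17.5 (log2 fold change -1.67 ± 0.07, adjusted p = 1.8e-08). NDN rose from 116 ± 26.1 to 179.9 ± 21.1 (log2 fold change 0.64 ± 0.17, adjusted p = 0.0141), a call that ended in every omission but that of control replicate 1 (adjusted p up to 0.281 without CSB replicate 1).

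In total 6706 genes changed in the CSB knockdown, 4191 up and 2515 down, so that 62.5% of the calls were rises, and the median tested gene lay 0.10 above control on the log2 scale. With edgeR's quasi-likelihood test and TMM scaling of the recovered reads, 7486 genes changed, 3624 up and 3862 down (48.4% rises), so the excess of rises depends on the scaling. Omission of a library gave 2478 (control replicate 1), 2167 (control replicate 2), 1907 (CSB replicate 1) and 2033 (CSB replicate 2) genes. camera called 22 of 34 lists, and 3 with an estimated correlation (p53 targets, cholesterol synthesis and S phase).

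**Figure D2:**
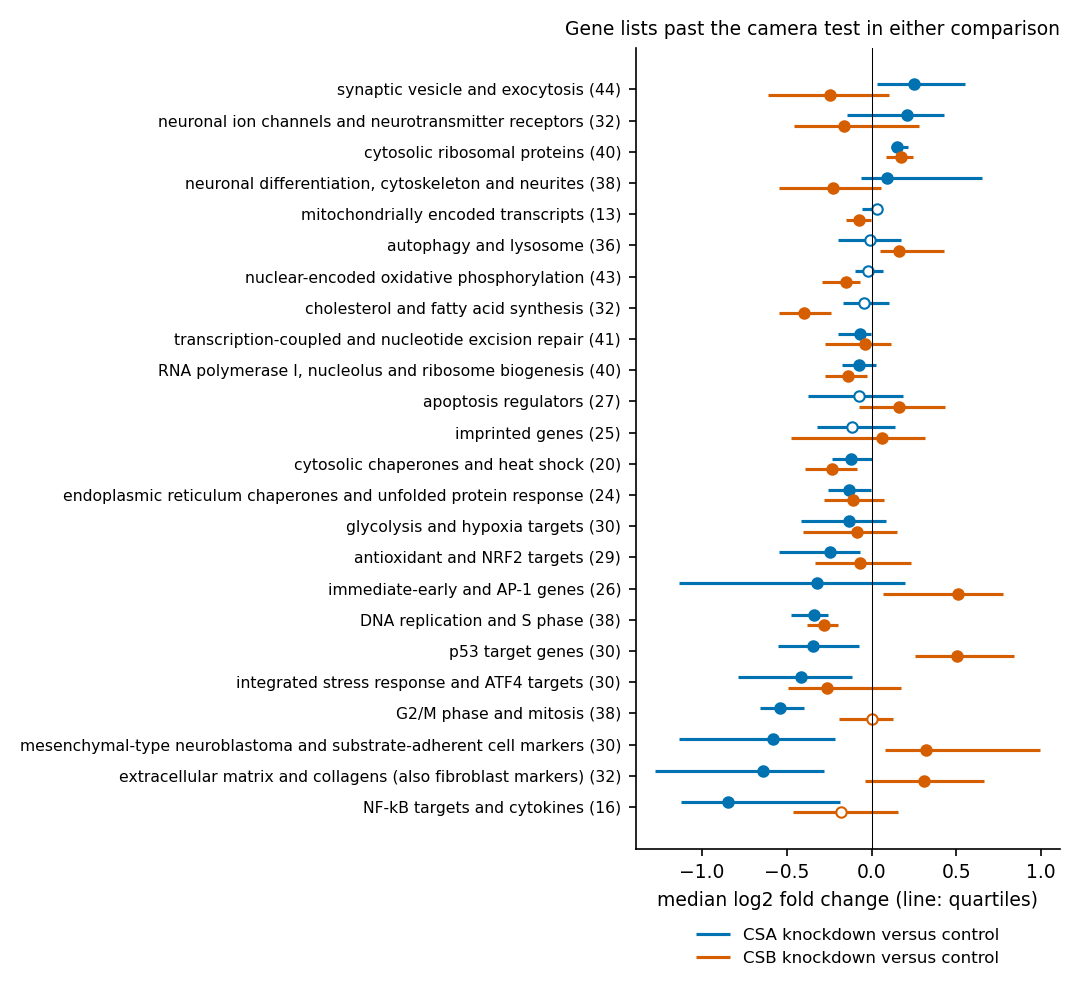
Log2 fold changes (x axis) of 24 gene lists in each knockdown versus control; points are list medians, lines run between the quartiles of the members, and filled points passed camera's test at its preset correlation and an adjusted p below 0.05, of which 0 in CSA and 3 in CSB passed with an estimated correlation. The p53 targets had medians of -0.35 in the CSA and 0.50 in the CSB knockdown, and the median over all tested genes was 0.00 in CSA and 0.10 in CSB; the excess of rises in CSB depended on the scaling.

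Compared directly with CSA knockdown cells, CSB knockdown cells had neuronal and cholesterol synthesis lists shifted down and p53 target, matrix, mesenchymal and mitotic lists shifted up by camera at the preset correlation. None of these shifts passed with an estimated correlation. INSM2 was at 2504 ± 2.52 in the CSA and 15.0 ± 0.963 in the CSB knockdown (log2 fold change -7.29 ± 0.09, adjusted p = 5.2e-13), IGF2 at 3678 ± 130.3 and 49.2 ± 1.98 (log2 fold change -6.19 ± 0.09, adjusted p = 5.6e-13). KIAA0125 differed by -6.30 ± 0.34. NEUROG2 (-8.94 ± 0.35) had a ratio of 0.000710 (95% interval 0.0000180 to 0.00396) and CCDC68 (-6.88 ± 0.39) one of 0.00299 (95% interval 0.0000754 to 0.0168). NGFR was higher in the CSB knockdown, at 1436 ± 111 against 54.8 ± 10.1 (log2 fold change 4.70 ± 0.13, adjusted p = 2.2e-10), as was CTGF, a secreted matrix-associated protein (log2 fold change 3.98 ± 0.30, adjusted p = 8.6e-07). From few reads, GIPC3 differed by 4.94 ± 0.50, a ratio of 51.1 (95% interval 13.8 to 427). The growth factor BMP6 (4.51 ± 0.56) had a ratio of 65.1 (95% interval 11.3 to 2607) and the fibrillin FBN3 (4.03 ± 0.57) one of 47.4 (95% interval 8.14 to 1909). The FBN3 call ended without either CSB library (adjusted p up to 0.0675).

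Of the p53 targets, 26 rose [23 to 25] and 1 fell [0 to 1] in CSB relative to CSA (adjusted p = 6.6e-17 by camera; adjusted p = 0.0503 with an estimated correlation), with a median of 0.92. Of the G2/M genes, 34 rose [23 to 31] and 1 fell [0 to 2] (adjusted p = 2.4e-15 by camera; adjusted p = 0.112 with an estimated correlation), and of the matrix genes, 26 rose [20 to 26] and 2 fell [1 to 2] (adjusted p = 1.0e-14 by camera; adjusted p = 0.0975 with an estimated correlation). FN1 differed by 2.19 ± 0.06. Mesenchymal markers (21 rose [15 to 18] and 1 fell [0 to 1], or 22 and 1 adjusted over the list alone; adjusted p = 3.8e-10 by camera; adjusted p = 0.0503 with an estimated correlation) and immediate-early genes (17 rose [12 to 17] and 5 fell [1 to 3]; adjusted p = 1.2e-04 by camera; adjusted p = 0.281 with an estimated correlation) shifted up as lists. So did autophagy genes (20 rose [11 to 18] and 5 fell [2 to 4], or 21 and 6 adjusted over the list alone; adjusted p = 0.00489 by camera; adjusted p = 0.132 with an estimated correlation) and apoptosis regulators (15 rose [11 to 13] and 5 fell [3 to 5]; adjusted p = 0.00988 by camera; adjusted p = 0.158 with an estimated correlation). The autophagy difference ended with RLE scaling (adjusted p = 0.0502), and the apoptosis difference without CSA replicate 1 (0.0702) or CSB replicate 2 (0.063).

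Synaptic genes shifted down as a list in the CSB relative to the CSA knockdown (27 fell [21 to 25] and 7 rose [4 to 6], or 28 and 7 adjusted over the list alone; adjusted p = 6.0e-12 by camera; adjusted p = 0.0787 with an estimated correlation), as did genes of neuronal differentiation (24 fell [19 to 22] and 8 rose [5 to 7]; adjusted p = 9.4e-09 by camera; adjusted p = 0.0503 with an estimated correlation). CHGA differed by -2.75 ± 0.06 and GAP43 by -2.72 ± 0.06. Ion channels (17 fell [14 to 16] and 9 rose [6 to 9], or 18 and 10 adjusted over the list alone; adjusted p = 3.8e-04 by camera; adjusted p = 0.104 with an estimated correlation) and cholesterol synthesis (22 fell [12 to 22] and 0 rose [0], or 23 and 2 adjusted over the list alone; adjusted p = 8.7e-13 by camera; adjusted p = 0.0503 with an estimated correlation) shifted down too, with HMGCS1 at -1.71 ± 0.06. Of 43 oxidative phosphorylation genes, 16 fell [4 to 11] and 4 rose [0 to 3], or 19 and 5 adjusted over the list alone (adjusted p = 2.7e-04 by camera; adjusted p = 0.448 with an estimated correlation; adjusted p = 0.0785 by fry). For cytosolic chaperones (9 fell [3 to 8] and 3 rose [3 to 4], or 10 and 4 adjusted over the list alone) the median was -0.13 and the mean 0.08. camera placed them lower (adjusted p = 0.0320; adjusted p = 0.281 with an estimated correlation), fry higher (adjusted p = 0.0295), and camera's call ended without CSB replicate 1 (0.0622). CRYAB, a member, was higher in the CSB knockdown (3.12 ± 0.28).

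No difference between the knockdowns passed camera for S phase genes (adjusted p = 0.726), DNA repair (adjusted p = 0.558), NF-kB targets (adjusted p = 0.0877) or ATF4 targets (adjusted p = 0.305). Antioxidant genes (adjusted p = 0.135), unfolded protein response genes (adjusted p = 0.342), glycolysis (adjusted p = 0.558) and imprinted genes (adjusted p = 0.272) did not pass either. Ribosome biogenesis (adjusted p = 0.143), ribosomal proteins (adjusted p = 0.538) and mitochondrially encoded transcripts (adjusted p = 0.0713) completed the set. In total 8340 genes differed, 5128 higher and 3212 lower in the CSB knockdown (61.5% higher), against 4491 and 4437 of 8928 with edgeR and TMM scaling (50.3% higher). Without CSB replicate 1 or 2 the total was 4003 or 4101. camera called 13 lists, and 0 with an estimated correlation, where 10 had an unadjusted p below 0.05; fry called 30.

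**Figure D3:**
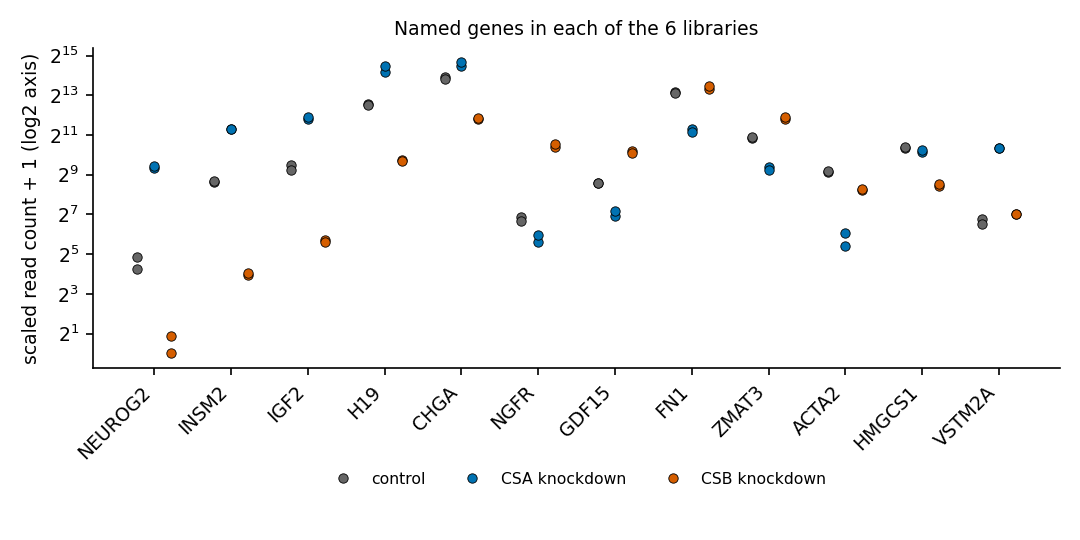
Scaled count + 1 (y axis, log2 scale) of 12 genes in each library, grouped by control, CSA and CSB knockdown on the x axis; each point is a library. IGF2, with means of 665, 3678 and 49.2, and CHGA stood above control in the CSA and below it in the CSB knockdown, and GDF15, with means of 380, 133 and 1124, the reverse.

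Some genes moved the same way in both knockdowns. IL32, a cytokine, fell from 148 ± 20.5 to 27.6 ± 3.93 in CSA (log2 fold change -2.38 ± 0.22, adjusted p = 1.1e-05) and to 27.1 ± 2.51 in CSB (log2 fold change -2.40 ± 0.22, adjusted p = 8.7e-06). CCL2, named from its list, fell in both. TNFRSF9 fell in CSB as well (log2 fold change -2.97 ± 0.49, adjusted p = 7.8e-04). From few reads, VWA5B1 fell to ratios of 0.115 (95% interval 0.0223 to 0.374) and 0.143 (95% interval 0.0363 to 0.409). IER3 had ratios of 0.0647 (95% interval 0.00154 to 0.417) and 0.0602 (95% interval 0.00144 to 0.387), and SLC22A11 went from 8 reads to 0 and 0, at least 1.29-fold and 1.36-fold lower against the floor. ARPP21 rose by 2.95 ± 0.28 in CSA and 1.91 ± 0.28 in CSB, and PTCHD1 by 4.79 ± 0.45 and 1.85 ± 0.45. NAT8 had ratios of 12.4 (95% interval 1.84 to 531) and 14.4 (95% interval 2.22 to 608). The histone gene HIST2H3A, with ratios of 18.6 (95% interval 2.94 to 777) and 12.5 (95% interval 1.88 to 532), and the pseudogene FGFR3P5, with 0 reads in control and 8 and 7 in the knockdowns (at least 1.39-fold and 1.08-fold higher), share sequence with relatives and are uncertain.

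The calls of IL32 and CCL2 in both knockdowns, and those of ARPP21 and PTCHD1 in CSA, held in every omission of a library. In CSA, the calls of VWA5B1, IER3 and NAT8 ended with the omission of any one of the 6 libraries (adjusted p up to 0.283, 0.158 and 0.148). Those of SLC22A11 and FGFR3P5 ended without either control or CSA library (0.0978 and 0.0950), and that of HIST2H3A in every omission but control replicate 1 (0.0823). In CSB, PTCHD1 lost its call in every omission but control replicate 1 (0.199) and VWA5B1 in every omission but CSB replicate 2 (0.195). TNFRSF9 and IER3 lost theirs without either control or CSB library (0.113 and 0.137), NAT8 and SLC22A11 without control replicate 1 or either CSB library (0.133 and 0.0787). HIST2H3A lost its call without control replicate 2 or either CSB library (0.128), FGFR3P5 without either control library or CSB replicate 2 (0.105), and ARPP21 without either CSB library (0.0568).

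In both comparisons with control, 858 genes rose and 699 fell, 1557 in all, where independent lists would share 351 and 262. Which direction held more depended on the scaling, with 668 up and 714 down after quantile normalization and 518 and 856 with recomputed size factors. In opposite directions, 389 rose in CSA and fell in CSB and 814 fell in CSA and rose in CSB, 1203 in all, where independence gives 210 and 437. The imbalance was smaller with quantile normalization (454 and 584) and with edgeR and TMM scaling (653 and 811). The expectations from independence are spread over all 28388 tested genes. Yet 1483 of the same-direction and 1166 of the opposite genes had a mean scaled count of at least 50. Genes with too few reads to be called lower these expectations, so an excess over them need not mean a link between the knockdowns. For the opposite set, INSM2, IGF2, H19, CHGA and GAP43 stood for the former kind, and ZMAT3, GDF15, VIM, SOX9, VCAN and NGFR for the latter. All of these also passed the direct comparison of CSB with CSA. That follows by construction, since in one fit this difference is the gap between 2 opposite fold changes, and it adds no support. In 50 simulated sets of unchanged libraries with shared controls, limma gave 0 genes in either category. With no gene changed, the adjusted p leaves hardly any calls to overlap, so this 0 is no chance value for the counts above. The controls were not split, since each part would hold 1 library, so some of the excess of same-direction genes may come from the shared controls. The fold changes correlated across 28388 genes with r = 0.260, against 0.494 in the simulations, with a covariance of 0.104 against 0.105. Over the 13397 genes with a mean scaled count of at least 50, r was -0.0437 against 0.498, with a covariance of -0.00703 against 0.00563. Genes are not independent replicates. The same-direction count was 272 and 235 without control replicates 1 and 2, 943 and 726 without CSA replicates 1 and 2, and 339 and 341 without CSB replicates 1 and 2. The opposite count was 275, 280, 700, 759, 335 and 334 in that order.

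**Figure D4:**
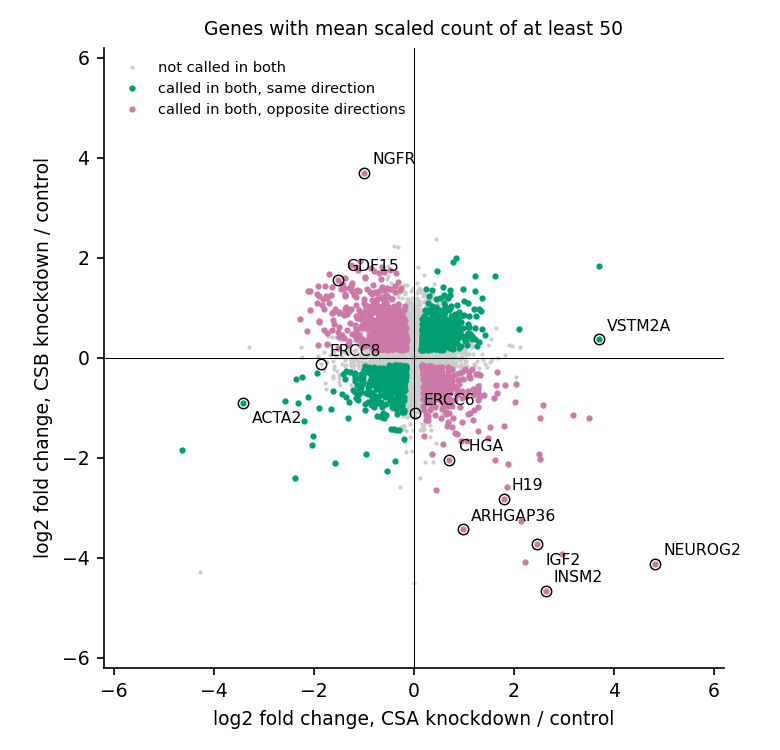
Log2 fold change versus control in the CSA knockdown (x axis) and the CSB knockdown (y axis) of 13397 genes with a mean scaled count of at least 50; each point is a gene, colored by whether it passed the test in both comparisons and in which directions. Of the genes shown, 1483 changed the same way and 1166 in opposite ways, with NEUROG2 and INSM2 far to the lower right; the count of rises in CSB depended on the scaling.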

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

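Count models (edgeR, DESeq2, limma-voom) on recovered reads, size factors recomputed over the 6 libraries and thinned reads were made alternatives after the data were seen. Only edgeR with TMM scaling had been named in advance, as the test for raw counts. limma without the trend called 1507 genes in the CSA knockdown, 1778 in the CSB knockdown and 4786 between the knockdowns, with 203 changed the same way and 217 in opposite ways. The cause was not tested. Fits of only the 4 libraries compared called 2460 in CSA, 5475 in CSB and 6256 between the knockdowns, with 660 the same way and 574 in opposite ways. All 3 fits hold fewer libraries, but CSA lost the largest share of its calls. The CSA libraries also differed most from each other (chi-square per degree of freedom 5.06, against 1.95 in control and 2.66 in CSB). The fit of 6 libraries gives all groups one spread, so its CSA count leans on the tighter groups. By construction, stricter thresholds called fewer. With a 2-fold change required these were 849, 926 and 2125, with 71 the same way and 89 opposite. At an adjusted p below 0.01 they were 3339 in CSA and 4384 in CSB, with 765 the same way and 694 opposite. With an unadjusted p allowed in one knockdown, 2506 changed the same way. Thinned to 19368272 reads per library, by which reads were removed, 1007 changed the same way. With a library omitted, its group's other library was assumed to vary like the other groups. Counts then ranged from 1512 to 2882 in CSA, 1907 to 5451 in CSB and 4003 to 6268 between the knockdowns. Those the same way ranged from 235 to 943 and those in opposite ways from 275 to 759. camera with an estimated correlation shifted 0 lists in CSA, 3 in CSB and 0 between the knockdowns, where the preset gave 18, 22 and 13. At an unadjusted p below 0.05 it gave 13, 12 and 10, and fry called 23, 26 and 30. Some estimates exceeded the preset of 0.01, as for G2/M (0.124), but those of p53 targets (-0.0281) and S phase (-0.0256) did not. Yet in CSA camera's unadjusted p went from 3.4e-10 to 0.0057 for p53 targets and from 1.1e-18 to 0.0019 for S phase. A larger correlation was thus not the cause for these 2 lists. With an estimate, camera takes its p from 3 degrees of freedom, and at the preset from far more. Failure to pass with the estimate therefore need not mean that correlation between genes undid a shift. Between the knockdowns, cytosolic chaperones reversed under fry (adjusted p = 0.0295; 0.00520 to 0.281 over 27 alternatives), for which the cause was not tested. In all, 47 counts moved by over 1.5 times, 45 of them down, and 180 did not. The share of rises moved by over 10 points in 12 cases, each downward, and not in 75. Named genes lost their call in 2280 cases, gained it in 2, kept it or stayed without one in 15881 and reversed in 0. List shifts were lost in 115 cases and kept in 1315. A replicate block called 5259, 6575 and 8258 genes, with 1493 the same way and 1166 opposite. Libraries with the same number did not deviate together (correlations -0.0402, -0.0323 and -0.0316). This check cannot show whether they were processed together. As to depth, simulated changes in genes with a control level from 10 to below 50 were recovered in 12.8% (CSA) and 38.2% (CSB) of cases, against 80.4% and 76.5% at 50 or above. Recovery of genes with a control level below 10, or at other depths, was not simulated.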

Other observations

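Tests chosen only after the result was seen were those of chromosome change as the source of most opposite genes, of scaling and of GC content. Lists not yet described passed camera's test in no comparison, although members moved. Of 22 neurotrophins and receptors, 6 fell [3 to 4] and 5 rose [1 to 2], or 7 and 5 adjusted over the list alone in the CSA knockdown (adjusted p = 0.715) and 8 rose [5 to 6] and 6 fell [2 to 5], or 10 and 6 adjusted over the list alone in CSB (adjusted p = 0.209). The CSA median was 0.02 and the mean -0.07. The receptor NTRK3 fell in both (-0.93 ± 0.06 in CSA and -0.58 ± 0.06 in CSB). Of 32 noradrenergic identity genes, 12 rose [9 to 10] and 11 fell [3 to 8], or 13 and 12 adjusted over the list alone in CSA (adjusted p = 0.235) and 15 rose [5 to 15] and 4 fell [3 to 6], or 16 and 4 adjusted over the list alone in CSB (adjusted p = 0.114). In CSB their median was 0.19 and their mean -0.03, with camera upward and fry downward. The receptor kinase RET rose in CSA (0.72 ± 0.05) and fell in CSB (-0.69 ± 0.05), and SATB1 did the reverse (-0.65 ± 0.05 and 0.81 ± 0.05). The noradrenaline transporter SLC6A2 rose in CSA from 2105 ± 40.2 to 5067 ± 110.2 (log2 fold change 1.27 ± 0.05, adjusted p = 1.4e-08), and SIX3 fell (-0.86 ± 0.05). Axon guidance and adhesion genes numbered 42. In CSA, 11 fell [4 to 8] and 10 rose [4 to 6], or 11 and 11 adjusted over the list alone (adjusted p = 0.884), and in CSB, 17 rose [11 to 17] and 9 fell [2 to 8], or 18 and 10 adjusted over the list alone (adjusted p = 0.0895). EFNB2 (1.66 ± 0.07) and ROBO2 (1.21 ± 0.08) rose in CSA and fell in CSB (-0.29 ± 0.07 and -0.69 ± 0.08). The CSB calls ended for EFNB2 with the omission of any one of the 6 libraries (adjusted p up to 0.183) and for ROBO2 without CSB replicate 1 (0.0589). SEMA5A fell in CSA (-0.86 ± 0.06) and rose in CSB (0.61 ± 0.06). The cadherin CDH11 rose in CSB (1.37 ± 0.05) and CNTNAP2 fell (-0.99 ± 0.06).

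Schwann, glial, endothelial, epithelial and immune markers did not pass camera's test. Of 13 Schwann and glial markers, 2 fell [1] and 0 rose [0] in CSA (adjusted p = 0.561) and 3 rose [1 to 2] and 0 fell [0], or 3 and 1 adjusted over the list alone in CSB (adjusted p = 0.611). PMP22 fell in CSA (-0.44 ± 0.07) and rose in CSB (0.80 ± 0.07). Of 14 endothelial and epithelial markers, 3 fell [1 to 2] and 1 rose [0 to 1], or 3 and 2 adjusted over the list alone in CSA (adjusted p = 0.792) and 1 rose [0] and 1 fell [1] in CSB (adjusted p = 0.985). KRT18 fell in CSA (-1.71 ± 0.19) and KRT19 in CSB (-1.68 ± 0.18). Of 7 immune markers, 1 fell [0] and 0 rose [0], or 0 and 0 adjusted over the list alone in CSA (adjusted p = 0.571) and 1 fell [0 to 1] and 0 rose [0], or 0 and 0 adjusted over the list alone in CSB (adjusted p = 0.976). PTPRC, the member that fell, had 6 reads in control, at the floor, and 0 in both knockdowns. Its call ended in CSA with the omission of any one library (adjusted p up to 0.146) and in CSB without either control or CSB library (0.122). Of 35 interferon-stimulated genes, 5 fell [0 to 2] and 2 rose [1] in CSA (adjusted p = 0.884) and 6 rose [0 to 4] and 3 fell [2 to 3], or 7 and 3 adjusted over the list alone in CSB (adjusted p = 0.450). IRF2 rose in CSA (0.58 ± 0.07). Of 26 genes of mitochondrial biogenesis and NAD metabolism, 6 fell [2 to 4] and 3 rose [0 to 1], or 6 and 6 adjusted over the list alone in CSA (adjusted p = 0.884) and 7 fell [3 to 7] and 4 rose [1 to 6], or 7 and 5 adjusted over the list alone in CSB (adjusted p = 0.0605). UCP2 fell in CSA (-0.67 ± 0.08), and PARP1 fell in CSB (-0.52 ± 0.05), where PINK1 rose (0.65 ± 0.09). Of 13 histone genes, 4 rose [3] and 4 fell [1 to 3], or 4 and 5 adjusted over the list alone in CSA (adjusted p = 0.884) and 3 rose [0 to 3] and 2 fell [0 to 3], or 4 and 3 adjusted over the list alone in CSB (adjusted p = 0.759). H2AFX fell in CSA (-0.64 ± 0.05). RNA polymerase II and elongation genes numbered 38, of which 4 rose [0 to 3] and 4 fell [0 to 3], or 4 and 5 adjusted over the list alone in CSA (adjusted p = 0.401) and 8 rose [1 to 10] and 6 fell [3 to 7], or 9 and 6 adjusted over the list alone in CSB (adjusted p = 0.933). The remodeller SMARCA5 fell in CSB (-0.67 ± 0.06) and the acetyltransferase CREBBP rose (0.48 ± 0.05). Between the knockdowns, adjusted p for these lists ran from 0.0556 to 0.826.

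Opposite movement of 1203 genes in the CSA and CSB knockdowns was weighed against depth, chromosome change and a shift of cell type. With libraries thinned to equal totals, 802 genes still moved in opposite ways, so unequal totals were not needed for a count of this size. That exceeded the 349 of independent lists, the bound set in advance. This bound also counts genes with too few reads to be called, so passing it decides little about depth. Of the 1203, 0.914% (11) lay on chromosomes or 20 Mb windows with a median shifted by over 0.2, which argues against chromosome change as the source of most. A chromosome gain or loss in one knockdown pool would shift its own genes against control in that knockdown only. By itself it would therefore not give opposite calls in both. Whether there was such a change stays open. Of 23 chromosomes 0, but of 145 windows, which stood in for arms, 3 passed that bound (-0.25 for chromosome 2 from 40 to 60 Mb, 60 genes, the farthest with at least 50). A shift between adrenergic and mesenchymal types may contribute and stays open too, since between the knockdowns mesenchymal genes shifted up at the preset correlation (median 1.02, adjusted p = 3.8e-10; adjusted p = 0.0503 with an estimated correlation) but the adrenergic list had a median of 0.16, a mean of -0.26 and adjusted p = 0.808. A difference between loss of CSA and loss of CSB, and off-target effects of single hairpins, were untested.

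Rises made up 62.5% of calls in the CSB knockdown. Median centring brought this to 55.1%, at the bound of 55% set for the test. The 6 scalings, this one included, gave 45.1% to 57.3%, and DESeq2 gave 43.3%. Size factors recomputed over the 6 libraries were 0.968 to 0.972 of the deposited ones in control and CSA, but 1.03 in both CSB libraries. The excess thus depended on the scaling, and which scaling is right stays open. With a GC trend removed the share was 63.2%, but that correction adds each library's mean back and decides nothing about the share, so GC content also stays open. Single calls did depend on it. With the trend removed, 5696 of the 6706 CSB calls, 7508 of the 8340 between the knockdowns and 5312 of the 5334 CSA calls were kept. Across 13345 genes, GC content and log2 fold change correlated at 0.289 in CSB (0.262 to 0.293 over pairs of single libraries) and 0.0749 in CSA, where CSA replicate 1 gave -0.0530 and -0.0190 and CSA replicate 2 gave 0.155 and 0.190 against the controls. An effect of CSB loss itself was untested.

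Genomic span was weighed because transcription blocks would be more frequent in long genes. The farthest correlation of span with log2 fold change over pairs of single libraries was -0.116, in CSB, where the other 3 pairs gave -0.0993, -0.0493 and -0.0343. In CSA the pairs gave 0.0238, 0.0460, -0.0783 and -0.0592. Of these 8 pairs, 1 passed the bound of 0.1, where all 4 of a knockdown were required, so a span effect stays open. An effect of CSA or CSB loss on elongation was untested.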
